A study of Homo sapiens with 52 samples.

How the data were processed

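RNA-seq and ChIP-seq libraries of MCF-7 cells were grouped by antibody, prolactin treatment and ACY-241 treatment from their titles, and doses and times were taken from the treatment labels. The labels' protocols state that cells were serum starved before treatment. For RNA-seq, they describe ACY-241 or DMSO exposure before prolactin or its vehicle was added.

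The submitters' processing notes name FastQC 0.11.2, fastp 0.20.1, Bowtie2 2.3.4.3, MACS2 2.1.1.20160309.6, deepTools, kallisto 0.46.0.4 and limma 3.38.3, and the builds hg38 and GRCh38. These notes, as used here, list the names and versions without a role or order for each. The table's name describes gene counts from kallisto, which estimates transcript abundance by pseudoalignment, with ribosomal RNA left out. How ribosomal RNA was left out and how transcripts were combined into genes are not given in the sources used here.

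The table holds 28226 gene names, each listed once, and 12 value columns. A column was to be used only where its name matched the label of 1 library. The name of each column was searched for in the labels of all 52 samples and in the series text, without regard to case, with Python 3.11.15. All 12 columns matched no label and were not used in any step, so 0 value columns were used. Assigning them by their order, or by the expression of genes that prolactin is known to change, would have assumed the outcome or an unrecorded key. The depth of each library is not reported for the same reason.

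A test with a shared estimate of spread over the 4 groups, processing alternatives and gene lists were fixed before the data were examined. None of them was run, and no statistic was computed.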

Results

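The series covers MCF-7 cells, an oestrogen receptor positive human breast cancer line, treated with prolactin, with ACY-241 or with both. Prolactin is a hormone whose receptor activates the kinase JAK2 and the transcription factor STAT5A. ACY-241, also called citarinostat, is an inhibitor of HDAC6, a mostly cytoplasmic deacetylase of tubulin and other proteins. HMGN2, the remaining protein studied, is a nucleosome-binding protein.

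Gene expression was profiled in 12 RNA-seq libraries that fall into 4 groups of 3 biological replicates. The control group received 0.1% DMSO. The prolactin group received DMSO and prolactin at 250 ng/mL for 120 minutes. The inhibitor group received ACY-241 at 2 µM, and the combination group received both agents at these doses. The treatment labels give 120 minutes for ACY-241 and for DMSO. Since the protocol describes this exposure before prolactin, these times may not be the total exposure in the groups that received prolactin. They list no DMSO for the groups that received ACY-241. Chromatin occupancy was profiled in 40 ChIP-seq libraries. They comprise 16 libraries for STAT5A, 16 for HDAC6, 4 for HMGN2 and 4 input libraries. The STAT5A and HDAC6 libraries cover 4 conditions each, with prolactin given for 30 minutes. The HMGN2 and input libraries listed here cover the DMSO control only. Each ChIP-seq condition has 2 biological replicates, each with 2 technical replicates.

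The design implies 6 comparisons of gene expression. Prolactin, ACY-241 and their combination are each set against the DMSO control. The combination is also set against ACY-241 alone, which gives the prolactin response in inhibitor-treated cells, and against prolactin alone, which gives the inhibitor response in prolactin-treated cells. The interaction asks whether the response to prolactin differs between cells with and without the inhibitor. None of these comparisons is reported here. The gene-level table lists 28226 genes in 12 value columns, and the names of all 12 columns occur in none of the sample labels used. No column was therefore assigned to a library, a treatment or a replicate. Neither the order of the columns nor the expression of any gene was used in place of a label. No expression value, library total, fold change or test is given for any gene, including STAT5A, HDAC6, HMGN2 and the known STAT5 target CISH. The ChIP-seq libraries were not analysed here.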

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

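The number of value columns matched to a sample label was 0 of 12 by exact name. It stayed at 0 of 12 under 3 looser matches, chosen after the column names were seen. These ignored punctuation, ignored punctuation and leading zeros, or searched for the letters of the name alone as a word. The other normalizations, filters on low counts and tests, the fits of fewer groups and the omission of single libraries fixed before the data were examined were not run, since no value was used. No paired analysis was possible, because no value column was assigned to a library and so to a replicate number.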
